A study of Mus musculus with 192 samples.

How the data were processed

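CD8 T cells were isolated from B16 melanomas of wild-type C57BL/6 mice and sequenced with Smart-seq2, per the labels. The reads were handled with Bowtie and RSEM and the mm10 build, per the submitters' processing notes; their versions and settings are not given in the sources used here. The values deposited by the authors are log2 values, log2(TPM + 1), where TPM is a gene's share of a cell's transcripts after division by its length. That unit was checked on the values: turned back to TPM, the table sums to between 806870 and 966420 per cell (median 950294), so that 3.36% to 19.3% (median 4.97%) of each cell's total lies in genes outside the table. TPM keeps no read depth, so the depth of each cell is unknown, and the precision given is that of counting cells. The table holds 12306 genes in 135 of the 192 labelled cells, and 80.3% of its values are 0. The 57 other cells were left out by the authors' quality filter, whose settings are not given in the sources used here. Of the gene names, 12103 matched a mouse symbol in the reference tables and 203 did not. No 2 cells had identical values, and the largest correlation between 2 cells was 0.560.

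A second table deposited by the authors names each cell's mouse and plate, per the file headers, and 3 other columns of it were not used. It holds 2 mice on 2 plates with 1 mouse per plate, library numbers 1 to 96 for mouse 1 and 289 to 384 for mouse 2, and all cells carry 1 sequencing run name. The authors' cell subtypes are not used here. No doublet caller was run, and doublets were not removed. Coordinates are those of the GRCm38 (mm10) annotation GENCODE M21, with Erdr1 from the RefSeq table of the same assembly.

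The design was fixed before the data were examined. It planned associations of genes with index measurements of surface proteins, or differences between classes where the index table gave classes. It gave mice, so the difference of mean log2 values, mouse 1 minus mouse 2, took that place. Part of the rule for named genes asked for the same sign in both blocks of library numbers, and this part could not be applied because the blocks are the mice. The rule otherwise named, among the 4424 genes detected in at least 20% of cells, the 12 with the highest and the 12 with the lowest difference that kept their sign after a linear term in the rank of genes detected. It also named the genes of the lists and of the joint detection pairs, and the 10 leading genes of each cluster. Some of these genes are not reported here. List genes given as examples in the text were picked after their values were seen.

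In all 27 gene lists were fixed before the data were examined: T cell identity, 15 lists of cell states and 11 of other cell types. The state lists are naive and memory, cytotoxic effector, short-lived effector, co-inhibitory receptors, exhaustion transcription factors, co-stimulatory receptors, tissue residency, S phase, G2/M phase, interferon response, glycolysis, oxidative phosphorylation, metallothionein and zinc, immediate early and stress, and apoptosis genes. The other types are CD4 T cells, gamma delta T cells, natural killer cells, B cells, macrophages and monocytes, dendritic cells, neutrophils, melanoma cells, fibroblasts, endothelial cells and red blood cells. A list is described by the median over its genes detected in at least 20% of cells, beside 10000 random lists of the same size matched on mean expression in 20 bins. No metallothionein gene passed that filter, so that list has shares of cells only. Percentiles describe these cells and are not p-values.

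A gene was detected in a cell with a value above 0, and shares have exact Clopper-Pearson 95% intervals. For a share of 0 the limit is 3 cells of the total. Co-variation of lists is Spearman's rho over cells between mean z-scores, with Pearson's r and with a partial rho given genes detected. Cells were clustered with the Leiden method at resolution 1 on a graph of 15 neighbours over 15 principal components of the 2000 most variable genes. A cluster was named when at least 3 markers of a list differed by more than 1 in log2 and more of that list's genes than of any other's were among its 10 leading genes.

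Several steps were chosen after the data were seen. Cells were clustered again without the genes of all lists, and differences were taken within each mouse and averaged over the 2 mice. The percentile beside such a difference was first taken over the pooled cells and then for the mean over mice, which moved the exhaustion transcription factors of group 1 from 66.9 to 98.9. Each joint detection gap was set beside the gaps of the same gene between cells with and without other genes. Those genes were detected in a share of cells within 5 percentage points of that of the receptor gene. The pairs of lists named in the text are 8 of the 91 computed, and the choice of these 8 was made with the values in view.

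Alternatives were detection above 1 or 10 TPM, a pseudocount of 10, no filter or a 50% filter on low genes, cells of each block alone, an upper quartile rescaling, a term for genes detected, leaving out cells with markers of another type, and other clustering settings and seeds. Added after the data were seen were the same filter at 10 TPM, leaving out the 10% of cells with the fewest genes detected, and the alternatives of the second clustering. The computations were tested on simulated data made from the real values of 4424 genes. The values of each gene were permuted over cells, so differences in depth between cells or plates were not part of the test. Of 200 genes moved by known amounts, 100% had the right sign of the recovered move, which is so by arithmetic and checks only the code. Of those moved by 2, 96% showed a total difference above 1, of those moved by 1, 82% showed more than 0.5, and of the genes not moved 6.25% exceeded 1 in size. Simulated lists of 10 genes each, 20 genes per pair, gave rho values of 0.895, -0.878 and 0.0717 for a shared, an opposite and no factor. Of the simulated clusters 3 of 3 were found. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0 and matplotlib 3.10.9.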

Results

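Smart-seq2, a full-length single-cell RNA sequencing method, was applied to CD8 T cells taken from B16 melanomas, a mouse skin tumour, of wild-type C57BL/6 mice. The labels list 192 cells, and the expression table holds the 135 that passed the authors' quality filter. Of the 96 cells of mouse 1, 74 were kept (77.1%), and of the 96 cells of mouse 2, 61 were kept (63.5%). Each mouse filled 1 plate, so mouse and plate cannot be told apart. The table gives 12306 genes in log2(TPM + 1), and a gene with a value above 0 is called detected. Between 1440 and 4220 genes were detected per cell, with a median of 2191 (2279 in mouse 1 and 2133 in mouse 2). The number of reads per cell is not known from these values. Shares of cells carry exact (Clopper-Pearson) 95% intervals, which cover counting error only. Cells of 1 animal are not replicates, so no p-value was computed, and differences between groups of cells are given as the mean ± SD over the 2 mice.

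The first question was whether the sorted cells carried the genes of CD8 T cells. Transcripts of a Cd3 chain, part of the T cell receptor complex, and of a Cd8 chain, the co-receptor of cytotoxic T cells, were found together in 98.5% of the 135 cells (interval 94.8 to 99.8). Cd8b1 was detected in 97% of cells, Cd8a in 87.4%, Cd3d in 95.6% and the receptor-proximal kinase Lck in 96.3%. Cd8a lies on chromosome 6 at 71373427 to 71379173 of the mm10 build. Nkg7, a cytotoxic granule gene, was detected in 95.6% of cells at a median of 6264 TPM where detected, and the chemokine gene Ccl5 in 85.9% at 5772 TPM. Among the 12 measured T cell identity genes the least often detected was Cd5, in 40.7% of cells. Genes of the metallothionein and zinc list were sparse: Mt1 was detected in 17.8% of cells, Mt2 in 7.41%, Slc30a1 in 2.22% and Mt3 in 1.48%.

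Markers of other cell types were searched in the same way. At least 2 markers of another type's list were detected in 88 cells (65.2%, interval 56.5 to 73.2), and in 15 cells (11.1%, interval 6.35 to 17.7) when only values above 10 TPM were taken. Most of the first number came from the neutrophil list, with 2 markers in 70 cells, in none of them above 10 TPM, which allows a share of up to 2.22%. The 2 genes behind it were low wherever they were detected: Cxcr2 had a median of 3.41 TPM in 84.4% of cells and Csf3r a median of 1.42 TPM in 57.8%. Above 10 TPM, 2 or more markers of dendritic cells were found in 8 cells, of macrophages and monocytes in 6, and of melanoma cells, natural killer cells and CD4 T cells in 1 cell each. Without the 10 TPM limit the numbers were 20, 8, 11, 1 and 5, in the same order. B cell markers met the criterion in 2 cells above 0 and in 0 above 10 TPM. The lists of fibroblasts, endothelial cells and red blood cells each had 1 gene in the table and no gene of the gamma delta T cell list was in it, so these 4 types could not meet the criterion. Tyr, the pigment-forming tyrosinase of melanocytes (chromosome 7, 87424771 to 87493512), was detected in 91.1% of cells at a median of 4.45 TPM, whereas the melanocyte genes Pmel and Tyrp1 were detected in 5.19% and 1.48%.

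The next comparisons asked which genes were detected in the same cells as the inhibitory receptor genes Pdcd1 (chromosome 1, 94038305 to 94052553) and Havcr2 (chromosome 11, 46454935 to 46481255). Havcr2 was detected in 45 of 72 cells with Pdcd1 (62.5%, interval 50.3 to 73.6) and in 4 of 63 cells without it (6.35%, interval 1.76 to 15.5). Tcf7, which encodes a transcription factor of naive and memory T cells (chromosome 11, 52252371 to 52283014), was not detected in any of the 49 cells with Havcr2, which allows a share of up to 6.12%, and was detected in 40 of the 86 cells without it (46.5%, interval 35.7 to 57.6). Among cells with Pdcd1, 11 of 72 carried Tcf7 (15.3%, interval 7.88 to 25.7), against 29 of 63 without Pdcd1 (46%, interval 33.4 to 59.1). That gap was -16.2 percentage points in mouse 1 and -50.1 in mouse 2.

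Other receptor and effector genes went with Havcr2. The inhibitory receptor gene Lag3 was detected in 95.9% of cells with Havcr2 (interval 86 to 99.5) and 29.1% of cells without it (interval 19.8 to 39.9). Entpd1, which encodes an ectonucleotidase, was detected in 65.3% (interval 50.4 to 78.3) and 14% (interval 7.42 to 23.1). The granzyme gene Gzmb was detected in 81.6% (interval 68 to 91.2) and 41.9% (interval 31.3 to 53), and the metallothionein gene Mt1 in 34.7% (interval 21.7 to 49.6) and 8.14% (interval 3.34 to 16.1). Tox, a transcription factor gene of chronically stimulated T cells, was detected in 66.7% of cells with Pdcd1 (interval 54.6 to 77.3) and 20.6% of cells without it (interval 11.5 to 32.7). The interleukin receptor gene Il7r was detected in 27.8% of cells with Pdcd1 (interval 17.9 to 39.6) and 52.4% without (interval 39.4 to 65.1). The intervals of Il7r met at their ends. For the proliferation marker Mki67 they overlapped, with 20.4% of cells with Havcr2 (interval 10.2 to 34.3) against 6.98% without (interval 2.60 to 14.6), and 16.7% of cells with Pdcd1 (interval 8.92 to 27.3) against 6.35% without (interval 1.76 to 15.5).

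Cells with these receptors had more genes detected, a median of 3028 with Havcr2 against 2040.5 without it and of 2671 with Pdcd1 against 2078 without it. Each gap was also ranked among gaps of the same gene between cells with and without other genes. These matched genes were detected in a share of cells within 5 percentage points of that of the splitting gene, Havcr2 or Pdcd1. The gaps of Lag3 and Entpd1 by Havcr2 lay above those by all matched genes, and that of Tcf7 lay below those by all 816. For Pdcd1 there were 440 matched genes. Havcr2 lay at percentile 99.8 there, Tox at 99.3, Tcf7 at 2.05 and Il7r at 2.27. Gzmb lay at percentile 99.9 and Mt1 at 97.9 with Havcr2. The gaps of Mki67 lay at percentile 91.4 with Havcr2 and 83.2 with Pdcd1. Each of these gaps had the same sign in both mice. The match was on the share of cells and not on the number of genes detected, with which Havcr2 had a rho of 0.553 and Pdcd1 of 0.341. The ranks thus do not remove the difference in genes detected between cells with and without the receptors.

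**Figure D1:**
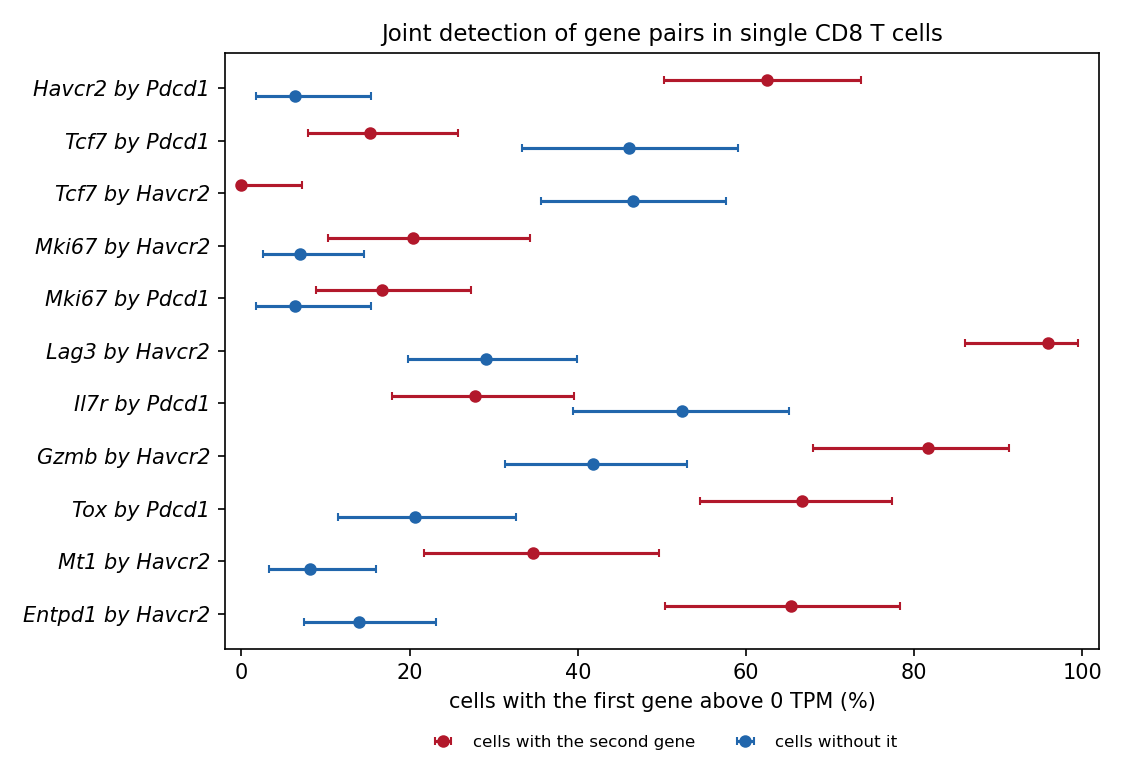
Percent of cells in which each gene was detected, among cells with (red) and without (blue) the receptor gene named after it, with exact 95% intervals as bars. Lag3 stood at 95.9% with Havcr2 and 29.1% without it, Tcf7 at 0% and 46.5%, and the bars of Mki67 and Il7r overlapped.

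Clustering on the most variable genes gave 4 clusters of cells. The largest, of 49 cells (36.3%, interval 28.2 to 45), was co-inhibitory receptors-like and was defined by Tnfrsf9, Lag3, Tpi1, Litaf, Klrc1, Rgs16, Irf8, Capg, Havcr2 and S100a4. A naive and memory-like cluster of 46 cells (34.1%, interval 26.1 to 42.7) was defined by Emb, Ccr7, Gpr18, Tcf7, Itgb7, Ly6c2, Il7r, Il4ra and S1pr1. A cytotoxic effector-like cluster of 35 cells (25.9%, interval 18.8 to 34.2) was defined by Gzmb, Ccl5, Gzma, Klrg1, Fasl, Rap1b, Cx3cr1, Itgb1, Gzmk and Ppp1r15a. The last 5 cells, 4 of them from mouse 2, stayed unnamed and were defined by Cish, Lgals3, Ergic3, Cd69, Il10ra, Gem, Dap, Gpr171, Efhd2 and Aurkaip1. The 3 larger clusters took 37.8%, 33.8% and 27% of the cells of mouse 1 and 34.4%, 34.4% and 24.6% of those of mouse 2. Their cells had a median of 3222, 2140 and 1640 genes detected. The number and the shares depend on the settings. At resolution 1.5 there were 7 clusters, with 19.3% and 18.5% of cells in those nearest the first and second. Without cell cycle genes the second held 21.5%.

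Because those genes made the clusters, the lists were compared between cell groups found without any gene of the lists, an approach chosen after the data were seen. It gave groups of 50, 42, 36 and 7 cells, and the first held all 49 cells of the co-inhibitory receptors-like cluster. The second shared 40 cells with the naive and memory-like cluster and the third shared 32 with the cytotoxic effector-like cluster. The third group is left unnamed, since as many short-lived effector as cytotoxic effector genes were among its 10 leading genes. The 7 cells of the last group include 1 cell of mouse 1, and their values were not compared. With 5% fewer or more variable genes, or without a random 5% of genes in 10 draws, there were 3 to 5 groups, and the adjusted Rand index with this partition was 0.702 to 0.892.

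In cell group 1, with a median of 3212 genes detected, inhibitory receptor, glycolysis and cytotoxic genes were higher than in the other cells of the same mouse. All 8 co-inhibitory receptor genes were higher in both mice, with a list median difference of 4.46 ± 0.39 in log2 (SD, n = 2 mice) against a median of 1.53 for random lists of similar expression (2.94 and 0.77 with a pseudocount of 10). Lag3 was higher by 6.93 ± 1.15, Havcr2 by 5.79 ± 0.64 and Pdcd1 by 5.76 ± 0.08. Tnfrsf9, a co-stimulatory receptor gene of recently activated T cells, was higher by 6.85 ± 0.03, and its list by 3.23 ± 0.59 (random median 1.83, percentile 98.2). All 10 glycolysis genes were higher in both mice, with a list median of 3.09 ± 0.31 (random median 1.28). Tpi1, a glycolytic isomerase gene, led them at 7.0 ± 0.41, and Gapdh, detected in nearly every cell, was higher by 1.88 ± 0.24. All 15 oxidative phosphorylation genes were higher in both mice, with a median of 2.84 ± 0.35 (random median 1.66, percentile 99.8), Cox5a by 4.12 ± 1.25.

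Among cytotoxic genes, the chemokine gene Ccl3 was higher in group 1 by 4.85 ± 0.74, the perforin gene Prf1 by 4.33 ± 0.64, the interferon gamma gene Ifng by 3.23 ± 0.34 and Gzmb by 2.68 ± 0.52. The list median was 2.95 ± 0.21 (random median 1.47, percentile 99.9). Exhaustion transcription factors had a median of 2.17 ± 0.00 (random median 1.06), at percentile 98.9, but at 66.9 when the cells of both mice were pooled. Among them Tox differed between the mice, at 6.13 in mouse 1 and 2.54 in mouse 2. Tissue residency genes had a median of 2.84 ± 0.08 (percentile 96.4), with Rgs2 higher by 4.34 ± 0.04 and Cd69 at -2.26 ± 0.11. S phase genes had a median of 1.75 ± 0.76 (percentile 95.6) and apoptosis genes 1.74 ± 0.41 (percentile 83.2). Genes of the naive and memory list were lower, with a median of -1.69 ± 0.75 against a random median of 0.98 and below all 10000 random lists. S1pr1, a receptor for exit from tissue, was detected in 2.0% of the cells of group 1 (interval 0.0506 to 10.7) and in 49.4% of the other cells (interval 38.4 to 60.5). The interferon response list was at 0.05 ± 0.17 where random lists had 1.42 (percentile 0.35), the immediate early and stress list at 0.18 ± 0.31 (percentile 0.70) and the short-lived effector list at 0.84 ± 0.50 (percentile 8.58). Several of these values moved in a fit beside the rank of genes detected. Oxidative phosphorylation had 1.19 there (percentile 95.3), co-stimulatory receptors 1.99, tissue residency 1.72 and naive and memory genes -3.10. The interferon list had -1.53 (percentile 0.080), immediate early and stress genes -0.25 (percentile 11.6) and short-lived effector genes -0.084 (percentile 15.9).

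Cell group 2 carried naive and memory genes. Their list median was 3.20 ± 0.05 higher than in the other cells (1.89 with a pseudocount of 10), above all 10000 random lists, with 10 of 11 genes higher in both mice. The lymph node chemokine receptor gene Ccr7 was higher by 4.64 ± 1.97, Tcf7 by 4.21 ± 0.35 and Il7r by 4.13 ± 0.61. Bach2, also of that list, differed by 0.27 ± 0.22 and had a median of 0.630 TPM where detected. Interferon response genes were higher by a median of 1.21 ± 0.93 (random median -0.37), at 1.87 in mouse 1 and 0.56 in mouse 2, with Rtp4 higher by 2.60 ± 0.20. Co-inhibitory receptor genes were lower, at -3.86 ± 0.37, as were cytotoxic genes at -2.99 ± 0.67, and both lay below all random lists. Gzmb was detected in 16.7% of group 2 (interval 6.97 to 31.4) and 74.2% of the other cells (interval 64.1 to 82.7), and it stood at -6.12 ± 1.47. Medians were also negative for exhaustion transcription factors (-1.49 ± 0.26), glycolysis (-1.40 ± 0.17) and tissue residency (-1.94 ± 0.79), at percentiles of 0.48 or lower.

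Cell group 3 had the fewest genes detected, a median of 1634.5 per cell, and the median difference from the other cells over the 4424 genes was -0.77. Against this background its cytotoxic genes stood out, with a list median of -0.08 ± 0.61 where random lists had -1.45, and of -0.75 against -1.98 after upper quartile rescaling. Of its 12 genes 3 were higher in both mice and 5 were lower in both. The same list was far higher in group 1, at 2.95 ± 0.21. The name of the cytotoxic effector-like cluster thus rests on its leading genes and not on the list as a whole. Immediate early and stress genes also lay high for their level, at -0.36 ± 0.19 against -1.12 (percentile 99). Gzmb was higher by 2.76 ± 1.60 and Ccl5 by 3.07 ± 2.58. Klrg1, a receptor gene of short-lived effector cells (chromosome 6, 122270596 to 122282882), was detected in 36.1% of group 3 (interval 20.8 to 53.8) and 3.03% of the other cells (interval 0.629 to 8.60). The shares of cells with Klrg1 and with the chemokine receptor gene Cx3cr1 differed between the mice, which had 20 and 16 cells in group 3. In mouse 1 Klrg1 was detected in 55% of group 3 and Cx3cr1 in 60%, and in mouse 2 in 12.5% and 25%. The median of the short-lived effector list, which Klrg1 does not enter because it was detected in under 20% of all cells, differed by 1.04 in mouse 1 and by -1.54 in mouse 2. Glycolysis (-2.21 ± 0.41), oxidative phosphorylation (-2.57 ± 0.79) and co-stimulatory receptor genes (-2.48 ± 0.53) were lower than the median of random lists, at -1.50, -1.60 and -1.58 (percentiles 5.46, 0.55 and 5.30). In a fit beside the rank of genes detected, the medians of 10 of the 15 lists in this group had the other sign, among them cytotoxic genes at 1.47, co-inhibitory receptors at 2.00 in place of -1.16 ± 0.30, and co-stimulatory receptors at 0.54. There the cytotoxic, co-inhibitory receptor and exhaustion transcription factor lists lay above all random lists. Glycolysis and oxidative phosphorylation lay at percentiles 89.3 and 70.1. Naive and memory genes, at -2.36, and interferon response genes, at -2.17, lay below all random lists there, against percentiles 87.4 and 16.1 as reported. Which lists lie high or low in this group thus depends in part on how the number of genes is treated.

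**Figure D2:**
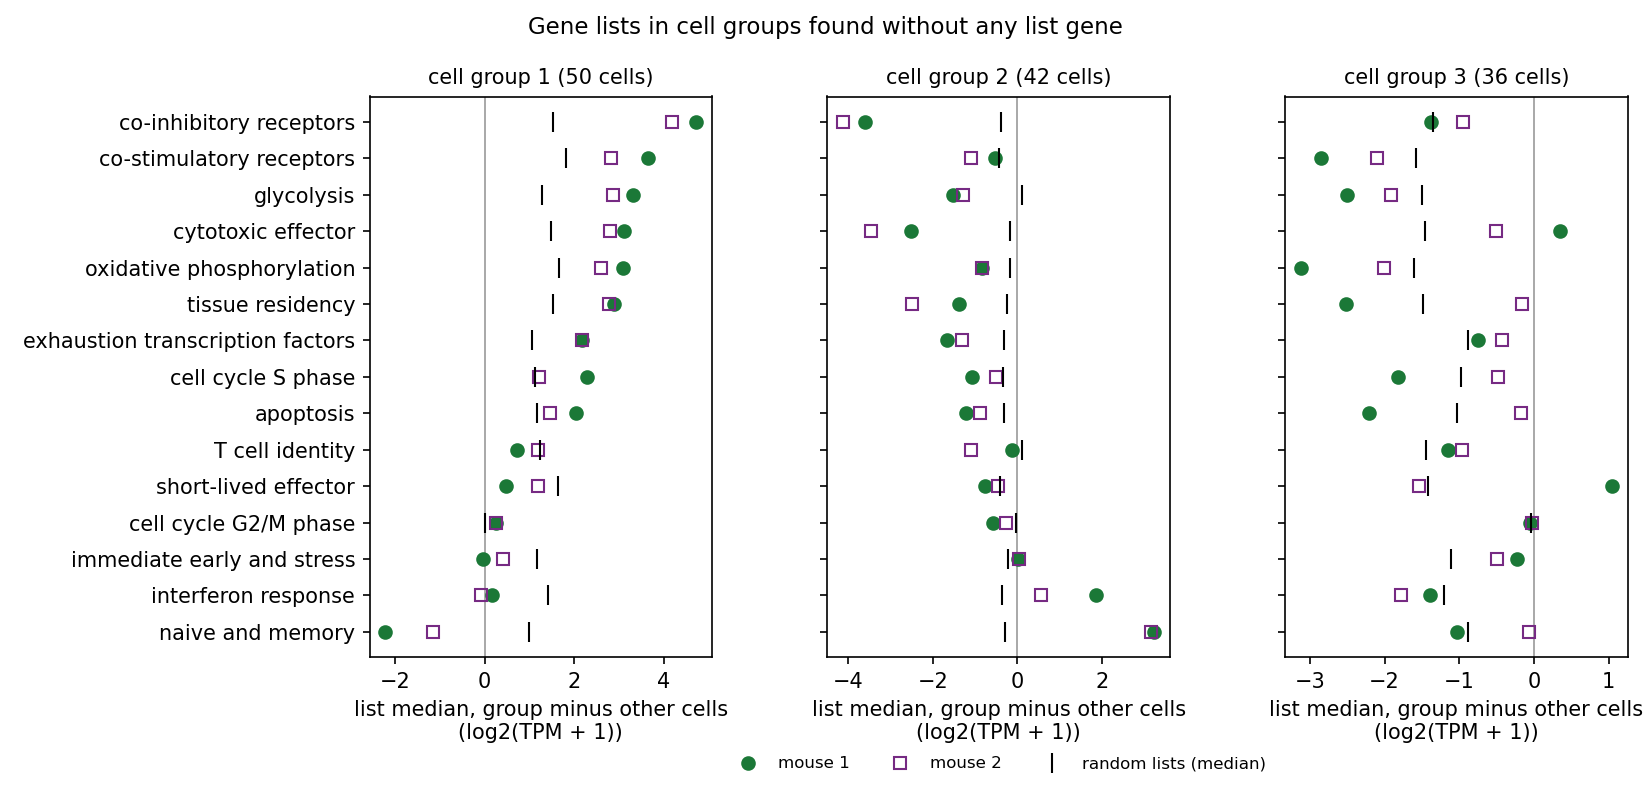
Median difference of each list between a cell group and the other cells of the same mouse, in log2(TPM + 1), for mouse 1 (circles) and mouse 2 (squares), with the median of random lists of similar expression as a tick. Co-inhibitory receptor genes stood at 4.73 and 4.18 in group 1, naive and memory genes at 3.24 and 3.16 in group 2, and cytotoxic genes of group 3 at 0.35 and -0.51, above a random median of -1.45.

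Across all 135 cells, the lists formed an axis between naive and memory genes and inhibitory receptor genes. Spearman's rho between the mean z-scores of the naive and memory and co-inhibitory receptor lists was -0.644, and -0.615 with the number of genes detected held fixed. It was -0.680 in mouse 1 and -0.612 in mouse 2, and -0.152 with the genes detected in at least 50% of cells, which leaves only Bach2 and Foxp1 of the naive and memory list. Cytotoxic and co-inhibitory receptor genes were high in the same cells, with a rho of 0.691 (0.656 with genes detected held fixed). Co-inhibitory receptors and exhaustion transcription factors had a rho of 0.700 (0.575), and co-inhibitory receptors and glycolysis 0.646 (0.442). Each of these 4 values lay beyond all 10000 pairs of random lists, whose median rho lay between 0.288 and 0.374. Pearson's r was -0.603, 0.685, 0.690 and 0.645 for the 4 pairs. It was -0.594, 0.686, 0.676 and 0.644 without the 2 cells farthest from the median score of the first list named in each pair. Cells far out on the second list alone were kept.

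The values of 4 further pairs were smaller. Co-inhibitory receptors and S phase genes had a rho of 0.331, which was 0.107 with genes detected held fixed and lay at percentile 60.7 of random pairs. Short-lived effector and co-inhibitory receptor genes had 0.195 (percentile 17.2), and naive and memory genes had -0.0336 with short-lived effector genes and -0.0150 with interferon response genes. Within cell groups 1, 2 and 3 the 4 larger values were smaller in size than across all cells, but short-lived effector with co-inhibitory receptor genes had 0.371 in group 2. Naive and memory with co-inhibitory receptor genes had -0.161, -0.440 and -0.484, cytotoxic with co-inhibitory receptor genes 0.597, 0.472 and 0.302, and co-inhibitory receptor with glycolysis genes 0.174, 0.229 and 0.0419. In all, 91 pairs of 14 lists were computed, and 76 had the same sign in both mice, or 61 with genes detected held fixed. The 5 genes of the G2/M list that passed the filter had median values of only 0.280 to 6.04 TPM where detected, so no division of cells is read from that list.

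The last comparison set the mice, which were also the plates, side by side, with no replicate of either. Erdr1 (X chromosome, 170010526 to 170018797, annotated as a transcribed pseudogene) was detected in 48 of 74 cells of mouse 1 (64.9%, interval 52.9 to 75.6) and in 0 of 61 cells of mouse 2, which allows a share of up to 4.92%. Cd3e (chromosome 9, 44998740 to 45009627), an invariant chain of the T cell receptor complex, had a mean log2 value of 4.25 in mouse 1 and 8.32 in mouse 2, a difference of -4.07. The neighbouring chains differed less, Cd3d with 9.15 and 9.71 and Cd3g with 8.91 and 10.20. Over the 4424 genes detected in at least 20% of cells the median difference, mouse 1 minus mouse 2, was 0.13, and these 2 genes had the largest. The next, Cirbp, which encodes a cold-inducible RNA-binding protein, stood at -2.97.

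Genes higher in mouse 1 included Nr4a1, a transcription factor gene induced by T cell receptor signals, with means of 4.75 and 1.99 in mice 1 and 2. The chaperone genes Hsp90aa1 (5.22 and 2.92) and Cct8 (5.86 and 3.37), and the co-chaperone genes Stip1 (4.07 and 1.85) and Chordc1 (3.45 and 1.29), were also higher there. So were Atp5d, an ATP synthase subunit gene, by 2.24, Bin1 by 2.23, Prr13 by 2.23, Cyth4 by 2.20, Map3k1 by 2.19 and the pore-forming gasdermin gene Gsdmd by 2.14. Higher in mouse 2 were the transcription factor gene Ets1 (5.22 and 8.0), the Ly6 family genes Ly6a (4.59 and 7.08), Ly6c2 (6.04 and 7.99) and Ly6e (8.04 and 9.86), the kinase gene Prkch (2.69 and 5.17) and the inhibitory receptor gene Tigit (5.01 and 6.90). Nol7 stood at -2.20, Sec24c at -2.04, Pfdn5 at -1.90 and Dpm3 at -1.86. The genes named here were picked for the size of their differences among 4424 genes. Intervals of the share of cells were computed for Nr4a1, Hsp90aa1, Ets1, Ly6c2 and Tigit. Only those of Nr4a1 stood apart, at 46.1 to 69.5 in mouse 1 and 15.8 to 39.1 in mouse 2. Those of Tigit were 51.5 to 74.4 and 62.7 to 85.5, and its SD over cells was 4.67 and 4.63.

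**Figure D3:**
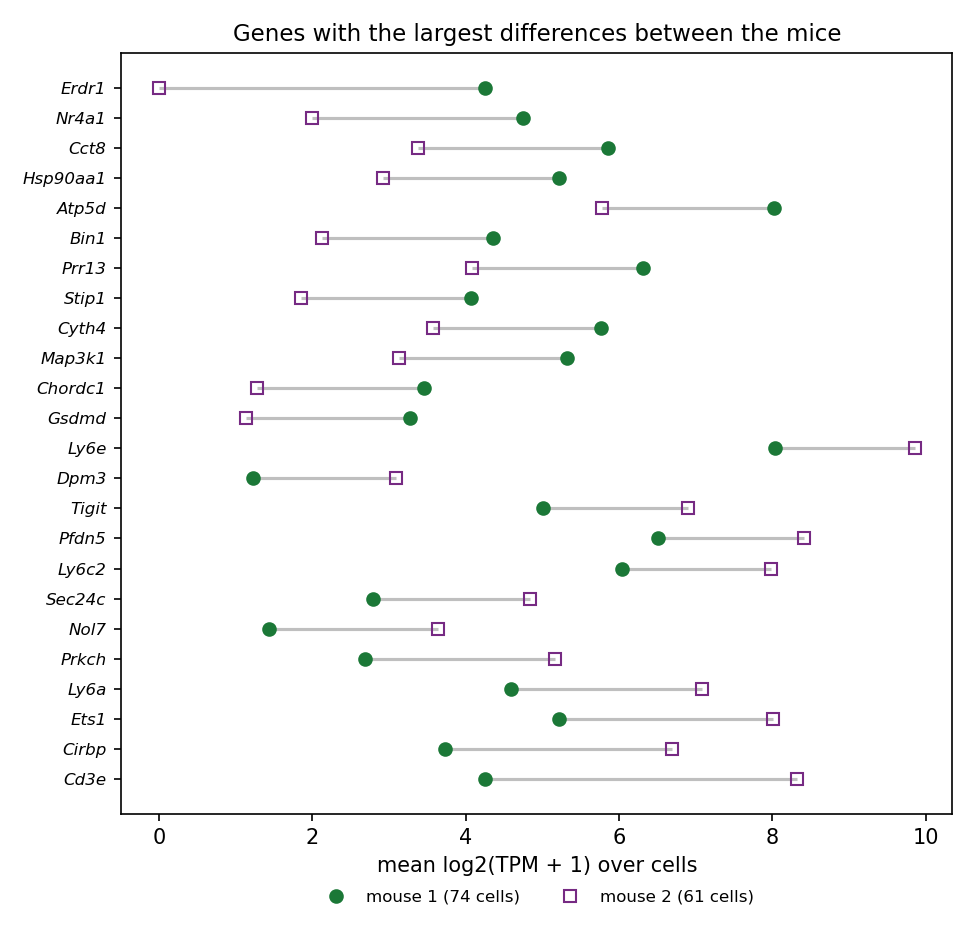
Mean log2(TPM + 1) of the 12 genes with the highest and the 12 with the lowest difference between the mice, over the 74 cells of mouse 1 and the 61 cells of mouse 2. Erdr1 stood at 4.26 and 0, and Cd3e at 4.25 and 8.32.

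Of the lists, interferon response genes were lower in mouse 1, with a median difference of -0.81 at percentile 0.060 of random lists. Irf7, a regulator of the interferon response, had means of 1.85 and 3.52, and Xaf1 of 1.31 and 2.70. Oxidative phosphorylation genes had a median of -0.41 (percentile 1.02), with Cox4i1 at 9.07 and 10.25 and, the other way, Atp5j at 6.01 and 4.75. S phase genes were higher in mouse 1, with a median of 0.77 (percentile 99.1), for example the polymerase clamp gene Pcna at 4.02 and 2.80, and so were apoptosis genes, with 0.87 (percentile 97.9), for example Bax at 4.48 and 2.94. The co-inhibitory receptor median was -0.38 (percentile 1.62), but the list was divided, with 4 of its 8 genes higher in mouse 1 and 4 higher in mouse 2. Entpd1, with 2.73 and 1.65, went against Tigit, and without the filter on low genes the median was 0.18. Naive and memory genes had a median of -0.23 (percentile 2.68), from Il7r with 2.06 and 3.78 to Klf2 with 2.14 and 0.81. The size of these medians depends on the processing. S phase had 0.24 with genes in at least 50% of cells and 0.45 with a pseudocount of 10, and naive and memory genes had -0.087 with that pseudocount. Interferon genes had -0.49 without the 10% of cells with the fewest genes, apoptosis genes 0.24 without the filter on low genes, and oxidative phosphorylation genes -0.66 beside genes detected.

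The remaining lists lay between percentiles 28.9 and 92.6 of random lists. Their medians were 0.46 for immediate early and stress genes, 0.45 for cytotoxic effector genes, 0.21 for exhaustion transcription factors, 0.20 for G2/M genes, 0.14 for short-lived effector genes, -0.01 for tissue residency genes and -0.07 for glycolysis genes. T cell identity genes had a median of 0.10 and a mean of -0.32, co-stimulatory receptor genes a median of 0.09 and a mean of -0.34, and tissue residency genes a mean of 0.06, so the sign of these 3 lists depends on the summary used. Other lists turned sign with the processing: cytotoxic effector to -0.071 without cells with markers of another type, glycolysis to 0.51 with the same filter, and exhaustion transcription factors to -0.029 and short-lived effector to -0.0082 beside genes detected. The filter on markers of another type leaves out 88 of the 135 cells. Of these, 70 carried the 2 neutrophil genes, which were low wherever they were detected.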

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

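The bound behind this result was chosen after the result was seen. The pair of naive and memory with interferon response genes had a rho of 0.102 across the cells of mouse 1 and -0.138 across those of mouse 2, opposite signs in the 2 animals. It was the single pair of 91 with opposite signs and at least 0.1 in size in both mice, while at a bound of 0.2, tried first, 0 pairs met the criterion. Both values are small and no interval was computed for them, so the opposite signs carry little weight. Pairs outside the bound differed more between the mice, such as short-lived effector with glycolysis genes at -0.0711 in mouse 1 and 0.477 in mouse 2. The difference between the mice was not tested, since each is 1 animal on 1 plate.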

How the results depend on the processing

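The alternatives of the cell groups found without list genes, the filter at 10 TPM, the filter on the 10% of cells with the fewest genes and the choice of pairs of lists were made after the results were seen. A value counts as moved when it changes by more than 0.1 in rho or log2, 10 percentage points, its exact interval, 1.5 times for a count, or the SD over mice for cell groups, and a sign counts as turned only where the value as reported had at least that size. The share of cells with a Cd3 and a Cd8 chain kept within its interval under all 5 alternatives, and the median number of genes detected per mouse within 1.5 times under the 1 alternative run. Leaving aside the main results, whose moves are all given below, 56 of 60 for single identity genes, 41 of 45 for joint detection, 39 of 44 for pairs of lists and 51 of 86 for lists between mice stayed within these limits, as did the number of cell groups under 12 of 12 small changes of the gene set. On the same basis, for named genes between mice 56 stayed, 88 moved and 0 turned sign, and for cell groups 217 stayed, 99 moved and 12 turned sign. The counts for cell groups include each mouse alone, which by arithmetic lies within the SD over 2 mice. Those alternatives could only count as stayed and say nothing about stability. Over all 91 pairs of lists, 752 of 976 alternatives stayed within the limit, 204 moved and 20 turned sign. Pearson's r and values within each block of library numbers could not be run for the difference between the mice, because the index table gives no number per cell and each block is a mouse. No paired analysis was possible because the cells of the 2 mice share no numbers and the result comes from no test, while the values of cell groups are differences within each mouse. Depth is unknown, and low values limit what detection shows.

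Cells with markers of another type made up 65.2%, and 45.9% above 1 TPM, 11.1% above 10 TPM and 23.7% without genes found in most cells at low values. The Tcf7 gap with Pdcd1 was -16.2 percentage points in the first block and -50.1 in the second, and that with Havcr2 -58.8 in the second. Between the mice, the naive and memory median was -0.087 with a pseudocount of 10 and -0.075 without the lowest 10%. The co-inhibitory receptor median turned to 0.18 with no filter, which lets in genes detected in few cells, and was -0.78 beside genes detected, -0.27 with a pseudocount of 10, -0.22 with the filter at 10 TPM and -0.97 for genes in 50% of cells. The S phase median was 0.64 beside genes detected, 0.45 with a pseudocount of 10, 1.04 and 0.65 with the filters on other cell types above 0 and 10 TPM, 0.90 without the lowest 10%, and 0.54 and 0.24 with no filter and the 50% filter. The interferon median was -0.57 with a pseudocount of 10, -0.95 without cells with other markers, -0.49 without the lowest 10%, and -0.52 and -0.62 with no filter and the 50% filter. Other medians of at least 0.1 turned sign between the mice: T cell identity to -0.069 beside genes detected, -0.66 without cells with other markers and -0.075 without the lowest 10%, cytotoxic effector to -0.071 without cells with other markers, short-lived effector to -0.0082 beside genes detected and -0.037 without the lowest 10%, and exhaustion transcription factors to -0.029 beside genes detected and -0.049 with the 50% filter. The cause was not tested.

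Among pairs of lists, the 50% filter, which leaves fewer genes, gave -0.152 for naive and memory with co-inhibitory receptors, 0.561 for cytotoxic with co-inhibitory receptors and -0.0255 in place of 0.195 for short-lived effector with co-inhibitory receptors. Co-inhibitory receptors with glycolysis had 0.442 beside genes detected and 0.353 without cells with other markers, a filter that gave 0.807 for cytotoxic with co-inhibitory receptors and -0.121 for naive and memory with interferon genes. That last pair had 0.102 and -0.138 in the 2 blocks. At resolution 1.5 there were 7 clusters in place of 4, with 19.3% and 18.5% of cells in those nearest the first and second, and without cell cycle genes the second held 21.5%. The 12 alternatives gave 3 to 7 clusters.

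For cell groups, co-inhibitory receptors in group 1 had 2.94 with a pseudocount of 10, 5.08 after upper quartile rescaling and 5.04 with groups found without the lowest 10%. Glycolysis there had 2.33, 3.94 and 2.74 in the same order and 2.56 beside genes detected. Naive and memory genes in group 2 had 1.89 with a pseudocount of 10, 3.04 beside genes detected, 2.97 at resolution 0.5 and 3.67 with groups found without the lowest 10%. Cytotoxic genes in group 3 had -0.75 after rescaling, 1.47 beside genes detected and 0.60 with groups found without the lowest 10%. Beside genes detected, 10 lists in group 3 had the other sign, and for 6 of them the value as reported was above its SD over mice, namely co-inhibitory receptors to 2.00, exhaustion transcription factors to 1.27, co-stimulatory receptors to 0.54, S phase to 0.40, G2/M phase to 0.48 and immediate early and stress to 0.26, and for the short-lived effector list in group 1 to -0.084. The G2/M median of group 3 also turned to 0.17 without the lowest 10% and 0.00137 with groups found without it, where interferon genes had 0.12. Immediate early and stress genes in group 2 turned to -0.091 after rescaling and -0.16 with groups found without the lowest 10%. The cause was not tested.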

Other observations

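The genes in the first 2 paragraphs and all tests of explanations here were chosen after the results were seen, except the test of shared sequence, whose bound was set before it was run. Outside the lists, 4290 genes were ranked by partial rho with a list's score, given the number of genes detected. Beside the co-inhibitory receptor score, the highest values were those of the galectin gene Lgals1 at 0.569 (0.422 in mouse 1 and 0.783 in mouse 2), the calcium-binding protein gene S100a4 at 0.541, the G protein regulator gene Rgs16 at 0.522 and the metalloprotease gene Adam8 at 0.513. Among the lowest were the ribosomal protein genes Rpl5 at -0.599 and Rpl12 at -0.552, each negative in both mice.

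The naive and memory score went with the embigin gene Emb at 0.594 and the receptor gene Gpr18 at 0.552, and with the ribosomal protein gene Rps24 at 0.557. The olfactory receptor gene Olfr1033 had 0.658 and Wdr92 0.615, and each was positive in both mice. The interferon score went with the guanylate-binding protein gene Gbp4 at 0.384, Epsti1 at 0.381 and Ifi47 at 0.367. Since TPM values of a cell share 1 total, a lower share of ribosomal protein genes and a higher share of other genes are not independent.

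Some genes were found at low values in most cells. Of the genes detected in at least 80% of cells, 64 had a median below 10 TPM where detected, among them Tyr and Cxcr2, which the lists hold as markers of other cell types. Repeated sequence shared between genes may account for part of this, since a median of 2.82% of their 25-base words occurred in at least 10 genes, against a median of 0.0210% in 10000 random lists matched on transcript length, all of which lay lower. Camk4, Mcmdc2, Nlrp1a, Ogdh and Spc24 had no such word in their longest annotated transcript, and other transcripts were not searched. Within the transcripts searched, words in at least 10 genes thus cannot be the reason for all 64. Sequence shared by fewer genes was not measured. RNA from melanoma cells is argued against for Tyr, because Pmel was detected in 5.19% of cells where Tyr was in 91.1%, and no biological explanation was tested.

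Cd3e and Erdr1 stood apart between the mice. The number of genes detected is argued against, as Cd3e kept -4.16 beside it. A test of a different mix of cell states over both genes at once was undecided; taken apart, it is argued against for Cd3e, whose smallest difference within a cell group was -3.24, and for Erdr1, detected in 72.4% of mouse 1 cells of group 1 against 0 of 21 cells of mouse 2. The bound for Erdr1 was set with these values in view, and in group 3, with 5 of 20 cells against 0 of 16, the intervals overlapped. A plate or library batch and a difference between the animals stay open and cannot be told apart, since there was 1 mouse per plate. Beyond the mix of cell states, no biological explanation was tested.

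Cytotoxic genes were high for their level in cell group 3, the cells with the fewest genes. The list lay at percentile 100 of matched random lists, at 0.35 and -0.51 in the 2 mice against a random median of -1.45. Low RNA yield alone stays open, because that percentile, the test written for it, is the pattern itself. Whether low yield lowers genes of similar expression alike was not measured. Beside the rank of genes detected the list stood at 1.47 against a random median of -0.43, above all random lists. Co-inhibitory receptors also lay above all random lists there and 10 of 15 lists had the other sign, so that fit does not decide the question. Immediate early and stress genes also lay high for their level in these cells, at percentile 99, and damage to the cells was not tested and stays open. No biological explanation was tested.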
